A study of Arabidopsis thaliana with 2 samples.

How the data were processed

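Leaves 5 to 9 of 4-week-old Arabidopsis thaliana plants in the Col-0 background were profiled by GMUCT, which maps uncapped and cleaved RNA across the genome. It is a method that ligates an adapter to RNA molecules carrying a free 5' phosphate and so reads the 5' ends of decay and cleavage intermediates. Per the labels, the plants are of the genotype ABI3:MTA, called mta, were grown at 22 °C with 16 h of light and 8 h of dark, and were harvested 4 h after first light. Adapters were ligated after 2 rounds of poly(A) selection, per the labels' protocols. MTA is the methyltransferase that writes N6-methyladenosine (m6A) in plant mRNA, and ABI3 is a regulator of seed maturation. There are 2 samples, both replicates of the same genotype. No wild-type library is used here.

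The authors deposited 1 table, in which both replicates are merged. Each line is a transcript model, and its last field lists the 5' end signal at each nucleotide of the genomic span, introns included. The unit of this deposited signal is not named. Of its 3250 distinct values, 3231 (99.4%) lay within 0.05 of a whole multiple of 6.2237, and the other 19 all stood for more than 16945 reads, where the deposited digits no longer resolve 1 read. Each value was therefore divided by 6.2237 and rounded, which gives whole numbers of 5' ends. What the authors' factor is relative to is not given in the sources used here. Per the submitters' processing notes, STAR 2.4.0, HTSeq 0.6.0 and the genome build TAIR10 were used. The trimming, the treatment of reads with several matches and the removal of duplicates are not given in the sources used here. The name of the table also mentions DMSO, which no label does.

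The table holds 13678 models of 9564 genes, and how these genes were chosen is not given in the sources used here. Coordinates below are those of the table, on TAIR10. Against the reference sequence used here, all 13191 nuclear coding models had ATG at their annotated start and a stop codon at their end. Gene symbols came from the lists fixed beforehand or from the RefSeq gene table, which matched 9359 of the 9564 genes. For each gene the isoform with the longest coding sequence (CDS) represented it. Plastid genes (88), mitochondrial genes (60), nuclear genes for which the table has no CDS (305) and 57 genes that shared over 50% of the shorter exon sequence with another gene on their strand were left out of the comparisons between genes. This left 9054 nuclear protein-coding genes. Exon positions shared by several genes were left out of counts per gene.

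Because both replicates are merged, no replicate error can be given and no test across samples was run. Shares have exact Clopper-Pearson 95% intervals, counts have exact Poisson 95% intervals, and frame shares and ratios have 95% intervals from 1000 bootstrap draws of genes. The first 2 kinds cover counting error only, since PCR reads without molecular identifiers are not independent molecules, and the bootstrap covers the choice of genes. Where a count was 0, the limit it allows was set at 3 counts of the total. Counts per gene were scaled to 1000000 5' ends of the 9054 genes (counts per 1000000, CPM). No RNA abundance was used here, so a high count can come from an abundant or from a fast decaying transcript. The median of each gene list was placed among 10000 random lists of the same size, with every member drawn from the 200 genes nearest in transcript length.

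Reading frames were numbered 1 to 3 by the codon base on which the 5' end lies. The stop codon ratio is the mean per position 17 and 16 nt upstream of the first base of the stop codon over the mean 50 to 20 nt upstream. The junction ratio is the mean 30 to 26 nt upstream of an exon junction over the mean 60 to 36 nt upstream, for exons of at least 60 nt. The same stop codon ratio was taken at the longest open reading frame of the 5' leader in genes listed for a conserved peptide upstream open reading frame (uORF). For 109 listed pairs of a small RNA and a target, the best ungapped site was taken in the representative isoform. A mismatch cost 1 and a G:U pair 0.5, doubled at nucleotides 2 to 13 of the small RNA, and no score limit was set. A cleavage peak meant that the base opposite nucleotide 10 held at least 10 ends and the highest count of the transcript. The background planned for it, positions shifted by 20 to 100 nt, cannot hold a peak in a transcript whose highest position is the site itself, so it was replaced by the best site of the same small RNA in random genes that are not listed targets, each drawn from 200 genes nearest in length. The RRACH ratio (R is A or G, H is A, C or T) is the mean 5 and 4 nt upstream of the central A in 3' UTRs over the flanks 50 to 20 nt away on both sides. RRBCH, with any other central base, was the control.

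The rule for named genes took the 20 genes with the most 5' ends, the highest, lowest and median members of each list, the 20 small RNA targets with the highest count at the site and all those with none, all measured uORF genes, and the 10 strongest single positions outside listed targets among genes with at least 100 ends. The genes MTA and ABI3 were to come first. Of the targets with none, 1 is not reported here by name. The lists, positions, tests and this rule were fixed before the data were examined. Set afterwards were the removal of overlapping genes, the minimum exon length, the lack of a score limit, the random genes for small RNA sites, the use of the small RNA targets as a gene list, the uORFs of other genes, the counts of genes and exons by their highest position, and the RRACH positions 3 nt upstream. Alternatives counted each occupied position once, left out the 1% of genes with the most 5' ends, took the first-numbered isoform, weighted genes equally, and changed backgrounds, thresholds or motif sets.

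The calculations ran in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and matplotlib 3.10.9 drew the plots. They were tested on simulated data, with Poisson counts drawn on the 9054 real transcripts. A junction ratio of 2.5 was recovered as 2.50, a stop codon ratio of 3 as 3.20, an RRACH ratio of 2 as 2.04, and all 15 cleavage peaks placed in 57 targets were found. Each placed peak was made the highest position of its transcript, so its recovery was certain and checks the calculation only. With no effect put in, the junction and stop codon ratios came out at 1.00 and 0.998, the RRACH ratio at 1.04, and 0 cleavage peaks were found.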

Results

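The data describe 5' ends of uncapped, polyadenylated RNA in leaves of mta plants, as 1 pooled library of 2 replicates. The table held 57928585 5' ends, of which 95.9% were in nuclear genes, 3.29% in plastid genes (95% interval 3.28 to 3.29%) and 0.781% in mitochondrial genes. The 9054 nuclear protein-coding genes carried 53591069 ends. A gene had a median of 1186.5 ends, the 10th and 90th percentiles were 241.3 and 8945.7, and 23.8% of exon positions held at least 1 end. Of the genes to be reported first, neither MTA (AT4G10760), the gene named in the genotype, nor ABI3 (AT3G24650), whose name the construct carries, was analysed here. With 1 pooled library there is no replicate check on any value below, and intervals cover counting error or the choice of genes as stated.

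The first question was where in transcripts the 5' ends lie. Coding sequence held most of them, 79.6%, close to its 76.3% of exon length. The 3' UTRs held 16.1% of ends (16.1 to 16.1%) on 14.3% of the length, a density 1.13 times the mean. The 5' UTRs were the poorest part, with 4.30% of ends on 9.46% of the length and a density of 0.455 times the mean. Positions that are intron in every model held 2.07% of the ends in nuclear gene spans, and exons were 25.7 times denser than introns. With introns taken from the representative isoforms of the analysed genes instead, parts of which are exon in another model, 69.5% of intron ends lay in the last 9 nt of introns of at least 60 nt. Leaving out the 1% of genes with the most ends (91 genes, which held 38.7% of the ends of the 9054 genes) moved the plastid share from 3.29% to 5.12%, and counting each occupied position once moved it to 0.554%.

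The next question was which genes gave the most 5' ends. TCH4 (AT5G57560, chromosome 5, 23307130 to 23308282), a touch-induced xyloglucan endotransglucosylase of the cell wall, led with 20469 ends per 1000000 (CPM, with an interval of 20431 to 20508). The metallothionein gene MT3 (AT3G15353) followed with 19708 CPM and SRC2 (AT1G09070) with 15147. Photosynthesis genes made up much of the remainder of the 20 highest. Among the light-harvesting genes LHCB2.1 had 12748 CPM, LHCB2.2 11589, LHB1B2 8579, LHCA4 8128, LHCA1 7526 and LHB1B1 7045. Of the other photosynthesis genes, PSBO1, of the oxygen-evolving complex, had 12193 CPM, PSBR 7399, the plastocyanin gene DRT112 6610, PSAF 5515 and RBCS1A, a small subunit of Rubisco, 5305. The remaining genes of the 20 were AT1G19020 with 11852 CPM, the aquaporin gene TIP2 with 9064, the mitochondrial carrier gene DIC2 with 7393, the transcription factor gene MYBR1 with 5723, ERD15 with 5388 and AT4G32020 with 5242 (5222 to 5261). Together these 20 genes held 19.3% of the ends. Reads of near-identical members of the LHCB, LHB1B and RBCS families may be counted at more than 1 copy, so their values are uncertain. When each position was counted once, 0 of these genes stayed among the 20 highest, since a gene then cannot exceed its length in nt.

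Gene lists differed widely in their 5' end counts. List values cover only the listed genes that were measured. All 21 measured nuclear photosynthesis genes lay above the gene median, with a list median of 2643 CPM against 26.6 in random lists, above all 10000 of them. They ran from LHCB2.1 (12748 CPM) through LHCA3 (2643) to GAPB (234). Salt and drought response genes had a median of 351 CPM, also above all 10000 random lists, and 8 of 9 lay above the gene median. ERD10, a dehydrin gene, had 4827 CPM, the cold-induced KIN1 351 and the sodium transporter gene SOS1 3.88. Housekeeping genes had a median of 133 CPM, at percentile 99.2 of random lists, from UBQ10 (5100) through ACT2 (133) to UBC21 (5.99), with 4 of 7 above the gene median. Of 10 listed defence genes, only 5 were measured. These had a median of 152 CPM at percentile 98.5, with 4 of 5 above the gene median. Among them the transcription factor gene WRKY33 had 1336 CPM, the immune regulator EDS1 152 and the defensin gene PDF1.2 3.77. That list fell to percentile 92.1 when 5' ends were taken per kb.

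The machineries of RNA modification and decay were not among the lists with many ends. Of 8 measured m6A genes, 2 lay above the gene median, and their median of 13.6 CPM stood at percentile 25.5 of random lists. The reader protein gene ECT2 had 175 CPM, the methyltransferase gene MTB 17.4, CPSF30 13.8, ECT3 13.4 and the demethylase gene ALKBH9B 2.58. RNA decay genes had a median of 29.8 CPM at percentile 77.1, with 9 of 13 above the gene median. They ran from DCP5 (110) through UPF3 (29.8) to VIP3 (6.12), and XRN4, the cytoplasmic 5' to 3' exonuclease, had 64.3 CPM. Clock genes had a median of 21.9 CPM at percentile 66.6, with 4 of 8 above the gene median, from GI (56.5) through CCA1 (22.3) and LHY (21.5) to PRR9 (2.58). Genes with conserved peptide uORFs had a median of 83.3 CPM at percentile 97.9, and 7 of 8 lay above the gene median. With each position counted once that percentile was 93.4. SAMDC1 was highest there (3340 CPM), BZIP2 and BZIP1 flanked the median (129 and 37.6), and NMT1 was lowest (7.30). The 57 measured small RNA targets had a median of 17.9 CPM at percentile 25.2, which became 4.16 with each position counted once. The seed, floral and TAS lists (8, 7 and 6 genes) were not analysed here.

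**Figure D1:**
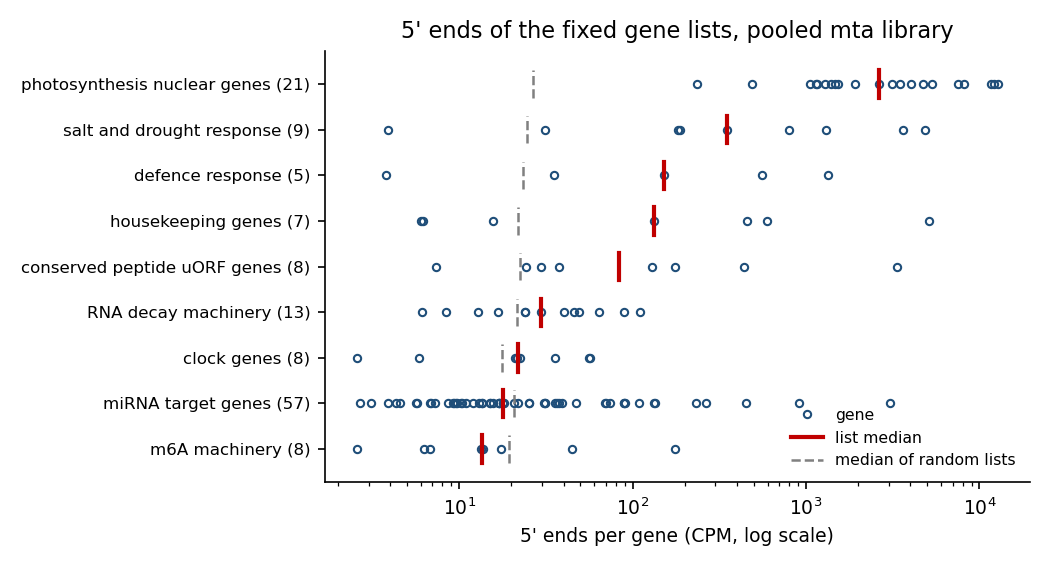
5' ends in CPM on a log axis for the measured genes of each fixed list (number in brackets), in the pooled mta library. Circles are genes, red bars the list medians and dashed grey bars the median of random lists; the photosynthesis median of 2643 lies far above its random median of 26.6, and the m6A median of 13.6 lies below its own of 19.3.

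Within coding sequences the 5' ends were unequally shared among the reading frames. Frame 1 held 29.2% of CDS ends (28.9 to 29.5%), frame 2 35.1% (34.8 to 35.3%) and frame 3 35.7% (35.4 to 36.1%). Frame 1 was the lowest of the 3 in 80.3% of the 5995 genes with at least 500 CDS ends.

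5' ends accumulated 17 and 16 nt upstream of stop codons, the known footprint edge of a ribosome with a stop codon in its A site. Pooled over the 9054 genes the ratio to background was 2.24 (1.94 to 2.65), and with each gene weighted equally it was 2.79 (2.69 to 2.89). Of 4846 genes with at least 50 ends in the 50 nt before the stop codon, 1473 (30.4%, 29.1 to 31.7%) had their highest position there, where equal positions would give 4%. Among genes chosen after their values were seen, the share of those 50 nt that fell on the 2 positions was 57.5% in SD1-29 (694 of 1207 ends), 48.1% in CYP707A3, which encodes an abscisic acid 8'-hydroxylase, and 47.9% in the jasmonate repressor gene TIFY10B (2694 of 5626 ends). With each position counted once, the ratio was 1.27.

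**Figure D2:**
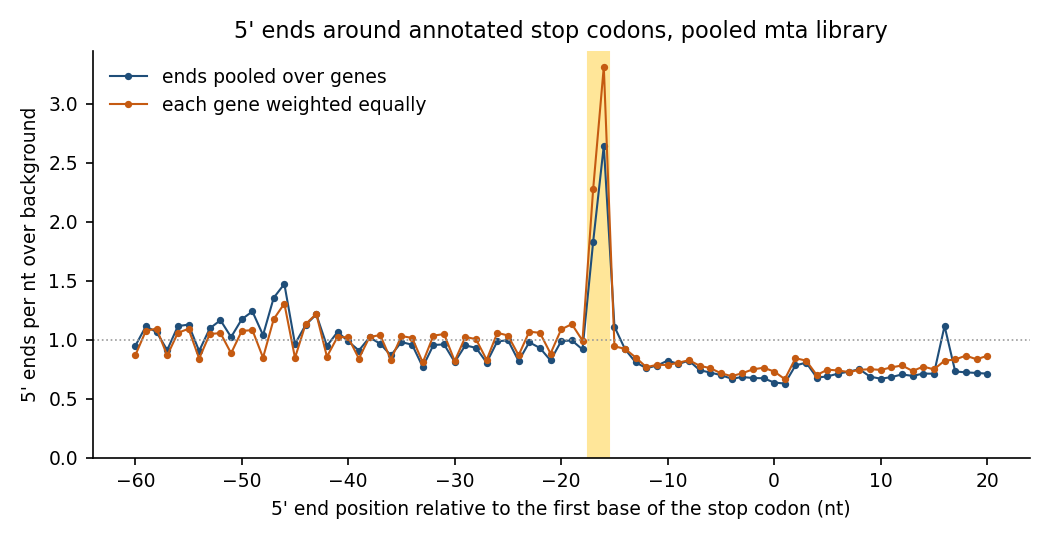
Mean 5' ends per nt over the background 50 to 20 nt upstream, against position in nt from the first base of the stop codon, in the pooled mta library. The blue line pools ends over genes and the orange line weights genes equally; the shaded positions 17 and 16 nt upstream average 2.24 and 2.79.

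A larger set of ends lay just upstream of exon junctions, where the exon junction complex sits on spliced mRNA. At 30 to 26 nt upstream of 52454 junctions in 8283 genes the ratio was 2.82 (2.61 to 3.06), and 4.28 (4.14 to 4.41) with genes weighted equally. Of 19618 exons with at least 50 ends, 5848 (29.8%, 29.2 to 30.5%) had their highest position in that window, where equal positions would give 3.49%. With each position counted once the ratio was 1.5, and at the first junction of genes with at least 3 junctions it was 1.54 (1.38 to 1.83). The last 7 nt of exons held 0.0259 times the background and the first nt of the next exon 2.94 times.

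**Figure D3:**
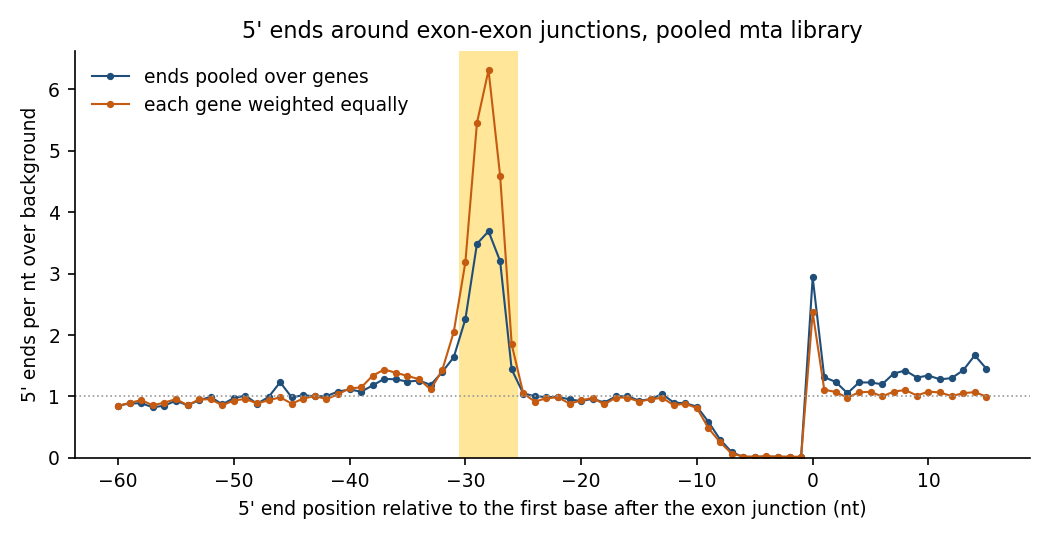
Mean 5' ends per nt over the background 60 to 36 nt upstream, against position in nt from the first base after an exon junction, in the pooled mta library. The blue line pools ends over genes and the orange line weights genes equally; the shaded window 30 to 26 nt upstream averages 2.82 and 4.28, and the last 7 nt before the junction hold almost no ends.

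The highest of the 3 footprint ratios was that at the stop codons of conserved peptide uORFs, peptides known to arrest ribosomes on the leader. Over 8 genes the ratio was 14.7 (5.81 to 26.5), and 6 of them had at least 10 ends at the 2 positions. BZIP53 (AT3G62420) had 101 and 371 ends 17 and 16 nt upstream against a mean of 8.65 per background position, a ratio of 27.3, with the nearer position at 23092485 on chromosome 3. The ratio was 25.4 in SAMDC2, 24.0 in BZIP1, 15.5 in BZIP2 and 4.56 in SAMDC1, a gene of polyamine synthesis. NMT1 had 12 ends 16 nt upstream against 4 in the whole background. HSFB1 had only 3 ends at the 2 positions (ratio 3.10), and SAC51 had 0 ends both there and in its background. The pooled ratio was 9.20 without BZIP53, 27.3 (16.3 to 37.0) with genes weighted equally and 1.63 with each position counted once. The longest leader uORFs of 3488 other genes gave a ratio of 0.701 (0.451 to 1.53).

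Cleavage guided by small RNAs was directly visible. Of 109 listed pairs, 57 had their gene in the table, and 21 of these showed a cleavage peak, from 13 of 24 small RNA families. When each of the 57 small RNA sites was sought instead in a random gene of similar length, 1000 draws gave a mean of 0.023 peaks and at most 1. The copper protein gene BCBP (AT5G20230), a target of miR398, had the most ends at its site, 44934 of 162558 (27.6%, 27.4 to 27.9%), at chromosome 5, 6826603, in the 5' UTR (site AGGGGGTGACCTGAGTTCTTC, 6826592 to 6826612). Its site has a poor score, 9.5, and among the other peaks CSD2 (10) and CCS1 (6) also scored above 5. The floral repressor gene TOE2 (AT5G60120) had 79.0% of its ends (78.0 to 79.9%) at the miR172 cut in exon 9, in the site ATGCAGCATCATCAGGATTCT on chromosome 5 (24210889 to 24210909). NAC1 (AT1G56010) had 76.7% (75.4 to 78.0%) at its miR164 cut in exon 3, in the site AGCACGTACCCTGCTTCTCCA on chromosome 1 (20947142 to 20947162).

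The other peaks covered several target families. AGL16 had 65.1% of its ends at the miR824 cut, AGO2 49.6% at that of miR403 (115 of 232 ends), HAM1 46.2% at that of miR171 and ARF17 44.5% at that of miR160. Among auxin receptor genes under miR393, AFB2 had 44.8%, AFB1 43.4% and TIR1 7.15%. AP2 had 38.1% at the miR172 cut, ORE1 24.8% at that of miR164, ARF3 21.7% at the tasiR-ARF cut and NFYA2 18.9% at that of miR169. The copper chaperone gene CCS1 had 8.73% and CSD2 10.2% at their miR398 sites. The CSD2 site lies 27 nt upstream of an exon junction, inside the window of the junction peak. SPL13A and SPL13B, near-identical copies, each had 566 ends at the miR156 cut and 396 on the next base, and their reads cannot be assigned to either. LCR had 6.73%, TCP4 5.61% and TCP3 8.94% of their ends at the cuts of miR394 and miR319. SPL2 had 156 ends at the predicted base and 297 on the next base, ARF16 96 and HAM3 81 ends at theirs, without a peak.

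At 10 sites there were 0 ends on the predicted base. PHO2 (miR399) had 0 of 5862 ends, which allows up to 0.0512% at that base, and TCP2 (miR319) 0 of 695. Only the best site of each transcript was examined, so a zero does not limit cleavage at any other site. ARF4 (tasiR-ARF) had 0 of 302 ends on the predicted base, but 5 ends 1 nt upstream and 1 end 1 nt downstream. CSD1 (miR398) had 0 of 4773 and DCL1 (miR162) 0 of 518, but the predicted cuts lie 4 and 1 nt before an exon junction, among the last 7 nt of exons where few ends are recorded, so these zeros set no limit on cleavage. The best ungapped sites in SPL4, GRF1 and GRF3, with 0 ends on the predicted base, scored 12, 9 and 9, and 1 nt upstream of that base lay 30 of the 463 ends of GRF1 and 38 of the 370 of GRF3. The miR166 site of ATHB15, with 0 of 545 ends, is split by an exon junction. So are those of PHV (13 of 2541 ends), PHB (7 of 801) and REV (3 of 305). In all of these the predicted cut is the first nt after the junction. Over all junctions that nt held 2.94 times the background, so ends there need not be cuts.

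**Figure D4:**
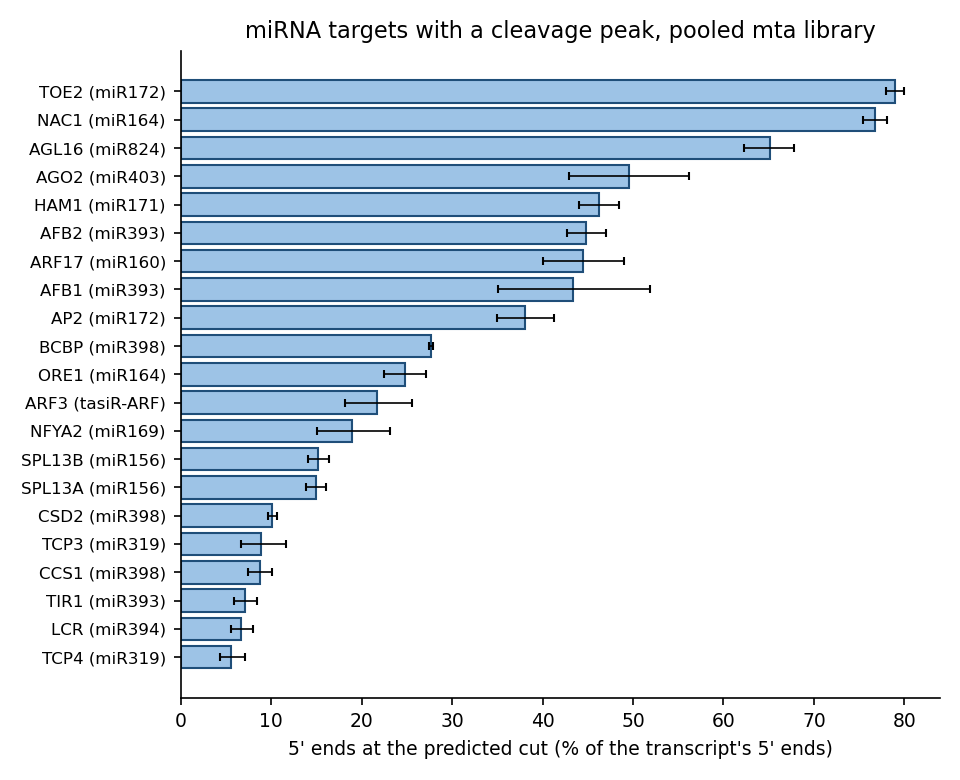
Share of each transcript's 5' ends that lie at the predicted cut, in percent, for the 21 targets with a cleavage peak in the pooled mta library. Bars are the shares and error bars exact 95% binomial intervals of counting error; the shares run from 5.61% in TCP4 to 79.0% in TOE2.

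A further comparison asked whether 5' ends gather just upstream of RRACH, the sequence in which m6A is written. At 29142 RRACH motifs of 3' UTRs the ratio 5 and 4 nt upstream was 2.01 (1.79 to 2.25), and at 54983 RRBCH motifs it was 1.09 (0.878 to 1.36). In coding sequences RRACH gave 1.19 (1.11 to 1.28) and RRBCH 1.02 (0.979 to 1.07). That RRACH value marks no local peak, since coding sequence stood at 1.21 at 15 nt upstream and 1.18 on the central A. Almost all of the excess in 3' UTRs was 4 nt upstream (2.94, 2.58 to 3.33), and the position 5 nt upstream stood at 1.08 (0.946 to 1.21). The position 3 nt upstream, not part of the planned window, stood at 2.11 (1.86 to 2.37). Whether this differs from plants with normal MTA levels was not analysed here.

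**Figure D5:**
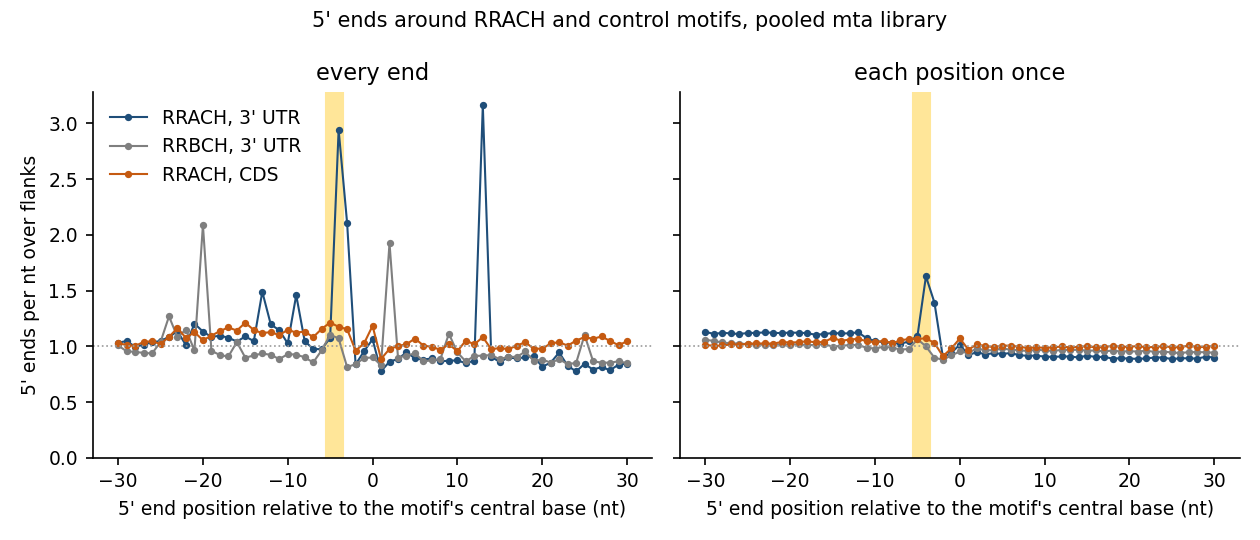
Mean 5' ends per nt over the flanks, against position in nt from the central base of the motif, for RRACH and RRBCH in 3' UTRs and RRACH in the CDS of the pooled mta library, with every end counted (left) and each position counted once (right). RRACH in 3' UTRs peaks 4 nt upstream at 2.94 and 1.63; the RRACH spike 13 nt downstream (3.16, and 0.907 without AT4G32020) and the RRBCH spikes 20 nt upstream and 2 nt downstream rest on that gene.

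The base at the 5' end itself differed little from transcript composition. G made up 23.2% of first bases against 22.7% of transcript sequence, A 30.3% against 28.5%, C 19.0% against 19.8% and T 27.5% against 29.0%. With each position counted once, G was 21.4% of first bases. Bases further into the read departed more from the 22.7% G of transcript sequence. At base 3 from the end, G made up 27.4% with every end counted and 25.04% with each position counted once. At base 5 it made up 26.7% and 24.6%. For an end 4 nt upstream of the central A of RRACH, base 3 is the first R. How far RRACH sites account for the excess of G was not tested.

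Some transcripts had most of their 5' ends at 1 nucleotide. The strongest outside listed targets was AT4G32020, with 208701 of 280899 ends (74.3%, 74.1 to 74.5%) at 15488820 on chromosome 4, in its 3' UTR 201 nt after the first base of the stop codon, where the sequence from the end reads TTCCCTTATTTTTTCAAGGGGCAAGATCGA. VTC4, an ascorbate synthesis gene, had 69.0% of its ends at 1 position, HPL1 67.8%, ATH1 67.7%, the response regulator gene RR3 62.2%, the clock gene PRR3 54.4% and AT5G27920 51.3%. In these 6 genes the position lies 27 to 29 nt upstream of an exon junction. AT1G31835 (59.6%) and AT1G72645 (57.9%) have 1 exon and so no junction. In HINT3 (54.6%) the junction nearest to the position lies 22 nt upstream of it. Of 8811 genes outside listed targets with at least 100 ends, 86 had at least 30% of them at 1 position. In 52 of the 86 it lay 30 to 26 nt upstream of a junction.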

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

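The tests of the motif ratios below were chosen after those ratios had been seen, and the tests of intron ends were set before their results were seen. In all, 4 signals outside the comparisons between genes were flagged because they stood above the limit that a count of 0 allows. Any class with more than 3 ends passes that limit, so the flag does not mark them as unusual. Plastid genes held 3.29% of the 5' ends, led by ATCG00480 with 589674 ends and ATCG00470 with 316356. Mitochondrial genes held 0.781%, led by ATMG00990 with 84790. Nuclear genes for which the table has no CDS held 575715 ends. Positions that are intron in every model held 2.07% of nuclear ends. In introns of at least 60 nt of the representative isoforms, parts of which are exon in another model, the last 9 nt held 879734 ends against 27309 in the first 9 nt and 306710 in the interior more than 20 nt from both ends.

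The intron ends belong with a gap at exon junctions: the last 7 nt of exons held 0.0259 times the background and the first nt of the next exon 2.94 times. A candidate explanation is the alignment of reads that start within a few nt of a junction, whose short upstream part does not suffice to place them across it. The excess on the first nt of the next exon made up 20.1% of the deficit of the last 10 nt of exons. Where such reads were extended into the intron, their ends would lie at its 3' edge. The last 9 nt of introns were 32.2 times denser than the first 9 nt (24.8 to 42.6). At positions 3 to 9 nt before the intron's end, the bases up to that end can equal the last bases of the upstream exon. Where they did, density was 38.9 times (32.5 to 47.6) that of other such positions. These reads may have been placed in the intron for want of a mismatch. Matching positions held 106680 ends and the others 89252. Distance was not matched and may account for part of the ratio, since ends fell from 92939 at 3 nt to 4584 at 9 nt. The positions 2 and 1 nt before the end, with 318491 and 365311 ends, were not covered. The test of intron edges could have come out the other way. The test of matching bases could have been passed through distance alone, so it does not decide whether the match played a part. No biological explanation was tested.

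In 3' UTRs, 5' ends lay 4 and 3 nt upstream of RRACH at 2.52 times the flanks (2.23 to 2.84). A preference for the bases around the central A alone is argued against by RRBCH, which gave 0.943 (0.751 to 1.21). RRBCH allows the same bases there, but their mix was not matched between RRACH and RRBCH. A few very high sites or amplified molecules as the whole cause are argued against by the ratio with each position counted once, 1.51 (1.49 to 1.53). A sequence preference of the 5' end or of ligation that acts alike in coding sequence does not account for the whole excess, since RRACH gave 1.16 there (1.09 to 1.25) and all 12 RRACH pentamers had lower ratios there than in 3' UTRs, with intervals apart. Such a preference stays open as part of the cause, because GGACT gave 1.39 in the CDS and GGAT, which is not RRACH, gave 1.53 in 3' UTRs, both with each position counted once. Whether reduced MTA activity in these plants plays a part also stays open, since the number of wild-type libraries used here is 0.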

How the results depend on the processing

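Of 61 alternative values, 20 stayed within the 95% interval of the reported value (for list percentiles, the exact interval over the 10000 random lists) or, for counts, within 1.5 times of it, and 41 moved. The 8 alternatives without AT4G32020 or BZIP53, in the first 50 codons, at the first junction, 4 and 3 nt upstream, with a score limit or for the list of small RNA targets were chosen after seeing the data. All ratios stayed above 1 and frame 1 stayed below an equal share. No paired analysis was possible because there is 1 genotype and both replicates are merged, which also rules out leaving out a replicate. Counting each position once caps high sites by construction. It gave 15.4% of ends in 3' UTRs, 0.554% in plastid genes, 0 of the 20 highest genes, 31.2% in frame 1, ratios of 1.27 at stop codons, 1.5 at junctions, 1.63 at uORFs and 1.36 at RRACH, 21.4% G, and list percentiles of 32.9 (m6A), 71.0 (RNA decay), 69.6 (clock), 97.7 (defence), 100 (housekeeping), 93.4 (uORF genes) and 4.16 (small RNA targets). Per kb the percentiles were 26.8 (m6A), 84.4 (RNA decay), 92.1 (defence), 98.8 (housekeeping), 99.3 (uORF genes) and 37.2 (small RNA targets). Without the 1% of genes with the most ends, 3' UTRs held 17.6%, plastid genes 5.12%, frame 1 28.8% and G 22.0%, and the ratios were 3.11 at junctions and 2.41 at RRACH. The first-numbered isoform gave 16.3% in 3' UTRs, and leaving out AT4G32020 gave 15.7%. With genes weighted equally frame 1 held 28.6%, and the ratios were 2.79 at stop codons, 4.28 at junctions and 27.3 at uORFs. Frame 1 held 32.1% in the first 50 codons. The wider stop codon background gave 1.87. The junction background that includes the last 15 nt of exons gave 3.56, and of those nt the last 7 lack ends as described above. The first junction gave 1.54. RRACH gave 1.19 in the CDS, 1.54 within 100 nt of the stop codon and 2.52 at 4 and 3 nt upstream. The cause was not tested elsewhere. Cleavage peaks numbered 18 to 29 under all 5 alternatives and 8 of the 10 strongest positions stayed with at least 500 ends. Depth limits sites in transcripts with few ends, such as ARF4, where 0 of 302 on the predicted base allows up to 0.993% at that base alone.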

Other observations

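The values in this part were computed after the planned results had been seen, while the prediction for the wound and touch genes was set before their counts were. 5' ends rose along transcripts: divided into 10 equal parts from the 5' end, the first held 3.38% of ends, part 8 21.6% and the last 5.23%. As a mean over genes the first held 3.32%, part 9 was highest with 21.7%, and the last held 11.2%. The first 10 nt of transcript models held 0.602% of ends on 0.538% of the length, a density of 1.12 times the mean against 0.455 times in 5' UTRs as a whole. The frame pattern was weaker early in the CDS. Frame 1 held 32.1% of ends (31.4 to 33.0%) in the first 50 codons and 28.7% (28.1 to 29.2%) in the last 50. Upstream of the stop codon a smaller peak 47 and 46 nt away stood at 1.26 (1.22 to 1.31) with genes weighted equally, 30 nt from the main peak, about the length covered by 1 more ribosome. Both positions lie in frames 2 and 3, which hold more ends, while the background averages all 3 frames. Singly they stood at 1.17 and 1.31, and the positions 44 and 43 nt away, in the same frames, at 1.13 and 1.22. How much of the ratio is the frame pattern was not tested. With genes weighted equally the stop codon ratio was 2.91 for TGA (2.76 to 3.05), 2.91 for TAG (2.68 to 3.15) and 2.55 for TAA (2.39 to 2.70).

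The exon junction ratio differed by place in the transcript. It was 1.46 (1.21 to 1.84) at junctions in 5' UTRs, 2.83 (2.61 to 3.07) in the CDS and 4.19 (2.68 to 6.16) in 3' UTRs. With genes weighted equally these were 1.56 (1.34 to 1.83), 4.38 (4.24 to 4.52) and 4.17 (3.43 to 5.07), so only the 5' UTR stood apart both ways. The pooled ratio was 3.52 (3.17 to 3.88) at the last junction of genes with at least 3. Among RRACH pentamers in 3' UTRs, with each position counted once, the ratio 4 and 3 nt upstream was highest at GGACT (1.96, 1.86 to 2.08) and AGACT (1.96, 1.87 to 2.03) and lowest at AAACC (1.18, 1.14 to 1.23). In the CDS GGACT gave 1.39 (1.37 to 1.41). GGAT, which is not RRACH, gave 1.53 (1.49 to 1.56) in 3' UTRs and 1.15 (1.14 to 1.16) in the CDS. Single sites could dominate a 3' UTR: 1352 ends of PDIL5-3, 77.9% of those in its 3' UTR, lay 4 and 3 nt upstream of an AGACT at 7186448 on chromosome 3, 1083 of 1399 in PRMT4A at an AGACA (77.4%) and 635 of 1049 in MYB65 at a GGACT (60.5%).

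AT2G25250, on chromosome 2, has its highest position in a stretch of 3' UTR like that of AT4G32020, with 2941 of 5784 ends (50.8%) at 10754519, where the sequence reads TTCTCTTATTTTTTCAAGGGGAAGATCGAA.

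Several of the genes with the most ends, TCH4 first, are known to respond within minutes to touch or wounding, which led to a list of 16 rapid wound and touch response genes chosen without them. Of these, 14 were measured, with a median of 532 CPM against 28.6 in random lists, at percentile 100. The zinc finger genes ZAT12 and ZAT10 had 2193 and 2172 CPM, the calmodulin-like genes TCH2 and CML38 1550 and 1510, WRKY18 980, MYC2 799 and ERF104, the lowest, 90.02. That percentile shows only that these genes had many ends. Handling at harvest may have raised these transcripts, a hypothesis that plants harvested without handling would have to decide and that stays open. Fast decay of the same transcripts at an unchanged level would also raise their 5' ends and cannot be told apart here because the number of RNA abundance tables used is 0.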
